A study of Capra hircus with 3 samples.

How the data were processed

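Single-cell RNA sequencing of dorsal skin was analysed from Albas White Cashmere goats, a breed kept for its fine undercoat. One library was made for each stage of the hair cycle: anagen, in which follicles grow, catagen, in which they regress, and telogen, in which they rest. Per the labels' protocols, skin of at least 3 females per stage was pooled before digestion with trypsin and collagenase, so animals cannot be told apart within a library, and the droplet libraries were made with a 10x Genomics kit for the 3′ ends of transcripts. Cell Ranger 2.2.0 is named in the submitters' processing notes. The genome build, the annotation and the filters on cells and genes are not given in the sources used here.

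The authors deposited 1 table of natural log values for all 3 libraries, with 17021 gene rows and 6439 cells. The cell names carry a prefix for each library, and 0 columns were left without a sample. Anagen and catagen names also share a first prefix that telogen names lack; what it stands for is not given in the sources used here. Each value was tested to be the natural log of the counts per 10000 counts of the cell plus 1: taking the exponential and subtracting 1 gave a sum of 10000 in every cell. Within a cell, 100% of the 15460922 values above 0 were whole multiples of the smallest, with a tolerance of 0.001, so whole counts and the total of each cell were computed back. That step takes the smallest value as 1 count, and at least 23.04% of the gene rows above 0 in any cell held it.

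The file does not pair its rows with gene names or identifiers: 0 rows carried one. A gene row is therefore named here only by its position in the table, and no gene was guessed. The cell type markers and gene lists chosen before the data were examined, the share of dermal papilla-like cells, the share of cycling cells and the comparison of gene lists could not be computed. Cell populations are given by number, and the rule for named genes, which asks for a symbol, was reduced to its conditions on size: at least 30 counts and a count in at least 5% of cells in the higher stage, ranked by the bound of the 95% interval of the ratio nearer to 1 and beyond 2-fold. It was applied to catagen against anagen, and 2 gene rows in each direction are given. After the data were seen it was restricted to gene rows above 0 in both libraries, which left 158 of 161 higher and 304 of 338 lower rows.

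The table looks like a merger of separately filtered libraries. The first 14457 gene rows were all above 0 in telogen and the remaining 2564 were all at 0 there; in anagen no gene row above 0 was found in fewer than 5 cells, against 21 gene rows in catagen and 25 in telogen. In all, 14004 gene rows were above 0 in each of the 3 libraries. A gene row at 0 throughout a library may have been removed from it, so such a row is said to be listed at 0, with no fold and no limit. Among the 2314 gene rows compared between stages over all cells, 1 was listed at 0 in a stage.

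Cells with 200 to 6000 detected gene rows were kept, a filter set before the data were examined. It left 2993 of 2999 anagen, 2634 of 2646 catagen and 788 of 794 telogen cells; all cells left out lay above the upper bound. The kept cells held 35921947, 27901161 and 10079121 counts. The lowest count of a kept cell was 2341 in anagen, 703 in catagen and 718 in telogen, so the libraries differ in how shallow a cell they list.

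Cells of the 3 libraries were clustered together with scanpy 1.11.5 and scikit-learn 1.9.0: natural log of counts per 10000 plus 1, 2000 variable gene rows chosen within libraries, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 with igraph 0.11.9, without batch correction. With 1 library per stage a correction could remove the stage difference. Without gene names the clusters were grouped by a step chosen after seeing the data: each was placed in the population, from Leiden clustering at resolution 0.1, that held most of its cells. Scrublet, run per library, called 10 of 6415 cells (0.16%) doublets. Whether the caller failed or the table lists few doublets cannot be told from so few calls, so doublets were kept and remain unresolved.

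Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals from scipy 1.17.1. Where a share is 0, the limit given is 3 cells of the total, a one-sided bound that is lower than the upper end of the exact interval. Intervals and limits cover counting error only, not the spread between animals or suspensions. No test between stages was possible with 1 library each, and no p-value is given. The mixing of stages was measured as the share of a cell's 15 nearest neighbours from its own stage, with equal numbers of cells drawn per stage. The planned ratio of summed raw counts was replaced, because the deposited values are not counts, by the mean over cells of counts per 10000, with no count model; summed recovered counts served as an alternative. Ratios between stages are on the log2(value + 0.1) scale over gene rows with a mean of at least 0.5 counts per 10000, which understates the change of low rows. Shares of gene rows beyond 2-fold describe size only. To compare the concentration of counts across depths, each cell was thinned to 1000 counts, which left out 0 anagen, 57 catagen and 18 telogen cells.

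The steps were tested on simulated data with the real totals per cell and 200 gene rows changed by known folds in each of catagen and telogen. All counts of the 6415 simulated cells were recovered from their log values. Over 2189 gene rows, 100% of those changed 3-fold were beyond 2-fold the right way in each of the 3 comparisons, 0% of those changed 1.5-fold were, and 0% of the unchanged rows were. These cells were drawn from 1 profile, so the test covers counting error and not differences between cells.

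Alternatives set before the data were examined were a minimum of 500 detected gene rows, doublets left out, Leiden resolutions of 0.5 and 2, each library clustered on its own, thinning before clustering, median-ratio scaling, totals without the 50 highest gene rows, and summed counts. Mitochondrial and ribosomal genes could not be taken out of the totals without names. Further alternatives were chosen after seeing the data: a common floor of 2341 counts per cell, the highest doublet scores left out, clustering without the 2645 gene rows that shifted at least 2-fold between stages in any of the 3 large populations, cluster 17 left out, no thinning, the scalings applied to the gene rows of population 3, and ratios within populations from 155 cells per stage thinned to 1000 counts, set beside 2 separate draws of anagen cells. The common floor was applied both with new clusters and, for the small populations and cluster 17, with the same clusters.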

Results

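The series asks, by its title, what dermal papilla cells do as hair follicles develop in cashmere goats. Dermal papilla cells are the mesenchymal cells at the base of the follicle. Dorsal skin was profiled in anagen, catagen and telogen, with 1 library per stage from pooled females. Because the table carries no gene names, neither dermal papilla cells nor any other cell type could be named, and the comparisons are between numbered cell populations. There are no replicates, so each difference is one between 3 libraries.

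The kept cells numbered 2993 in anagen, 2634 in catagen and 788 in telogen, with 35921947, 27901161 and 10079121 counts. Median counts per cell were 8605, 7080 and 9327, and median detected gene rows 2287, 2064 and 2290.5. Shallow cells were spread unevenly: 2.47% of anagen cells had fewer than 1000 gene rows, against 18.87% in catagen and 20.56% in telogen. The lowest count of an anagen cell was 2341, against 703 in catagen and 718 in telogen.

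The first comparison asks which cells made up the skin at each stage. The 29 clusters fell into 12 populations, and populations 1, 2 and 3 held 92.17% of the 6415 cells. Population 1 made up 53.29% of anagen cells (95% interval 51.48 to 55.09), 41.88% of catagen cells (39.98 to 43.79) and 19.92% of telogen cells (17.19 to 22.89). Population 2 went from 27.3% in anagen (25.71 to 28.93) to 43.36% in catagen (41.45 to 45.27) and 40.48% in telogen (37.03 to 44.0), where the intervals of catagen and telogen overlap. Population 3 was at 12.8% in anagen (11.62 to 14.05), 6.68% in catagen (5.76 to 7.7) and 28.05% in telogen (24.93 to 31.32). The stage order of populations 1 and 3 was the same in clustering without the gene rows that shifted between stages, where population 1 was at 53.39, 43.39 and 19.42% and population 3 at 12.8, 6.68 and 27.92%. Those clusters were placed by the main population that held most of their cells, and 98.25% of cells stayed in theirs. The same order is therefore no separate support. Digestion of the tissue and the lowest count listed in each library can set such shares.

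**Figure D1:**
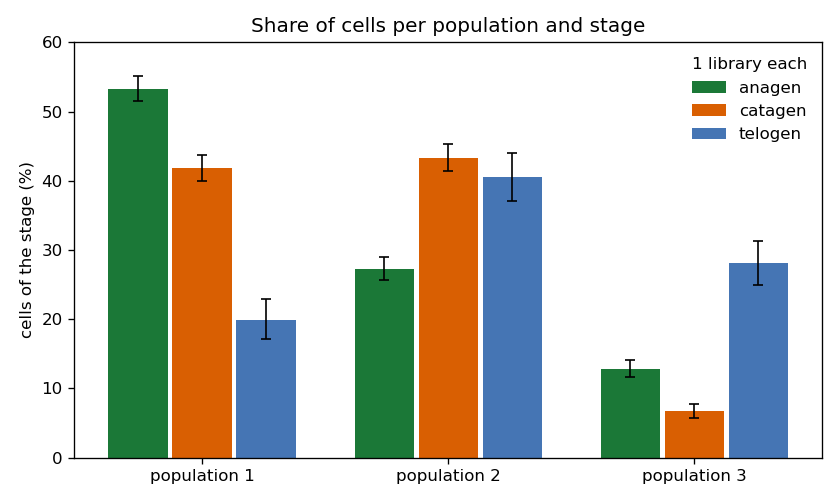
Bars give the share of each stage's cells (percent, vertical axis) in populations 1, 2 and 3, with 1 library per stage; error bars are exact 95% binomial intervals for counting error only. Population 1 runs from 53.29% in anagen to 19.92% in telogen, and population 3 is at 28.05% in telogen against 6.68% in catagen.

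Population 1 in telogen was made up of unlike cells. Of its 157 cells, 81 belonged to cluster 17, with a median of 1977 counts, and the other 76 had a median of 30447.5. Cluster 17 held 10.28% of telogen cells, 1.47% of anagen cells and 0.65% of catagen cells. Among cells above the lowest anagen count it held 4.67% of telogen cells (3.17 to 6.6), 1.47% of anagen cells and 0.14% of catagen cells. Without it, population 1 was at 10.75% of the telogen cells that were left.

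The 9 small populations together held 6.62% of anagen, 8.09% of catagen and 11.55% of telogen cells. Population 5 was at 0.43% in anagen (0.23 to 0.74), 2.01% in catagen (1.51 to 2.62) and 1.02% in telogen (0.44 to 1.99). Most of its catagen cells were shallow: among cells above the lowest anagen count, 15 of its 53 catagen cells were left and it was at 0.72% in catagen (0.4 to 1.18) and 0.93% in telogen (0.34 to 2.02), intervals that overlap that of anagen. Population 9 was at 0.23% in anagen (0.09 to 0.48), 1.06% in catagen (0.71 to 1.53) and 0.51% in telogen (0.14 to 1.29), and its cells put a median of 69.5, 60.1 and 30.8% of thinned counts into 10 gene rows, over 7, 26 and 4 cells. Population 8 held 0 of 2993 anagen cells, which allows a share of up to 0.1%, against 0.61% in catagen and 4.19% in telogen. Its median of 1664 counts lies under the lowest count of any anagen cell, 2341, and the upper quartile of its telogen cells, 2452, lies above it. The limit therefore covers only cells as deep as those listed for anagen; among such cells population 8 was at 0.1% in catagen (2 cells) and 1.4% in telogen (9 cells).

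Population 11 was found in anagen alone, with 24 cells or 0.8% of the library (0.51 to 1.19). It held 0 of 2634 catagen cells, which allows up to 0.114%, and 0 of 788 telogen cells, which allows up to 0.381%. With 1 library per stage, a population of 1 library may be that library rather than a cell type. The 50 gene rows at 10 or more counts per 10000 and at least 10-fold above anagen cells of populations 1, 2 and 3 took 19.53% of its counts, and 28 of them were listed at 0 in both other libraries. The leading one of these 28, row 16359, named after its values were seen, was at 909.04 counts per 10000 in population 11. It was also at 4.66, 5.89 and 6.43 counts per 10000 in anagen cells of populations 1, 2 and 3, where 97.7, 95 and 96.9% of cells held a count, at median depths of 13997, 6480 and 6955 counts.

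The second comparison asks how far cells of one population differed between stages. With 788 cells drawn per stage, 69.2% of the nearest neighbours of anagen cells, 71.6% of those of catagen cells and 76.1% of those of telogen cells came from the same stage, where equal mixing gives 33.3%. With cells thinned to 1000 counts the shares were 54.3, 63.26 and 66.49%. Population 3 parted most. With 157 cells per stage, its own-stage shares were 93.2% in anagen, 84.9% in catagen and 83.3% in telogen, against 59.4, 68.8 and 70.4% in population 1 and 52.9, 61.7 and 66.7% in population 2. In population 3, neighbours of catagen cells from another stage were mostly telogen cells, at 13.4% against 1.7% from anagen.

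The clusters showed part of this parting. At equal weight of the libraries, 11 of the 29 clusters, with 38.91% of the cells, took at least 75% of their make-up from 1 stage. These were 6 of the 11 clusters of population 1, 0 of the 6 of population 2, 3 of the 3 of population 3, and the single clusters of populations 8 and 11. Anagen cells of population 3 lay in clusters 14 and 19 (260 and 112 of 383 cells), which held 0 catagen cells and 6 telogen cells together, while cluster 7 held all 176 catagen cells and 215 of the 221 telogen cells. Catagen and telogen cells of population 3 were therefore not parted by cluster. The lead of telogen in cluster 7, 79.46 against 19.46% for catagen, goes with the share of population 3 in those libraries, 28.05 against 6.68%. In population 1, clusters 2, 11 and 16 held mainly anagen cells and clusters 10 and 13 mainly catagen cells. Cluster 10 made up 10.33% of catagen cells and held 0 of 2993 anagen cells, which allows up to 0.1%.

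**Figure D2:**
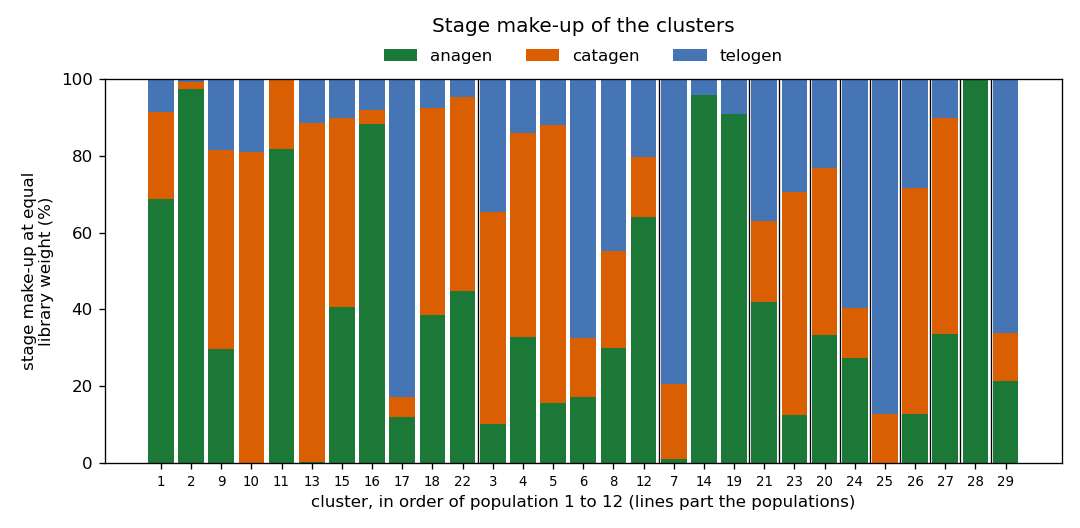
Stacked bars give the make-up of each of the 29 clusters by stage in percent (vertical axis) after the 3 libraries were given equal weight; clusters are ordered by population and lines part the populations. All 3 clusters of population 3 (7, 14 and 19) take at least 75% from 1 stage, and none of the 6 clusters of population 2 does. Cluster 7 holds all 176 catagen cells and 215 of the telogen cells of population 3, so its lead of telogen does not part those stages.

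The third comparison concerns how many counts cells yielded and how these were spread over gene rows. Counts per cell also depend on how deeply each library was sequenced, which was not examined, so they do not measure RNA content. Populations 2 and 3 had their lowest median counts in catagen: 6480, 4012.5 and 10811 counts in population 2 and 6955, 2612.5 and 11015 in population 3, in anagen, catagen and telogen. Above the lowest anagen count of 2341 the medians were 6480, 5600.5 and 11829 in population 2 and 6955, 3754 and 11658 in population 3, so part of the gap between anagen and catagen came from the shallow cells listed. Population 1 had 13997, 16248 and 3436, but without cluster 17 the order turned and telogen was highest, at 14434, 16303 and 30447.5. Above the lowest anagen count, with cluster 17 kept, telogen was also highest, at 13997, 16956 and 24020. In population 3 the 10 leading gene rows of a cell thinned to 1000 counts took a median of 26.3% of counts in anagen (quartiles 21.1 and 32.15), 15.4% in catagen (13.1 and 18.2) and 29% in telogen (14.6 and 38.85). Unthinned medians were 26.23, 15.05 and 28.17%. The 11 anagen cells placed in cluster 7, with all catagen cells, had a thinned median of 17.6%; clusters were made from the same values, so this does not say where the gap lies. In population 1 the thinned medians were 11.8% at each stage, but without cluster 17 they were 11.8, 11.8 and 10.55%. In population 2 they were 13.3, 12.1 and 12.3%. Catagen cells of population 3 also spread over more gene rows, with 591 per 1000 counts against 497 in anagen and 509 in telogen.

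The leading gene rows of population 3 were largely shared. Of the 10 highest in anagen, 8 were among the 10 highest in catagen and 10 in telogen. The highest row of each stage took 7.31% of counts in anagen, 1.82% in catagen and 9.48% in telogen. Whether these are the same row was not examined. The 152 gene rows at least 10-fold higher in population 3 than in populations 1 and 2, as means over the stages, summed to 3112.59 counts per 10000 in anagen, 2044.03 in catagen and 3317.39 in telogen. They did not move one way: 100 of them stood at least as high in catagen as in anagen, with 39 at least 2-fold higher and 23 at least 2-fold lower. With median-ratio scaling 77 stood at least as high, 16 were at least 2-fold higher and 31 lower, so which direction prevailed rested on the scaling.

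**Figure D3:**
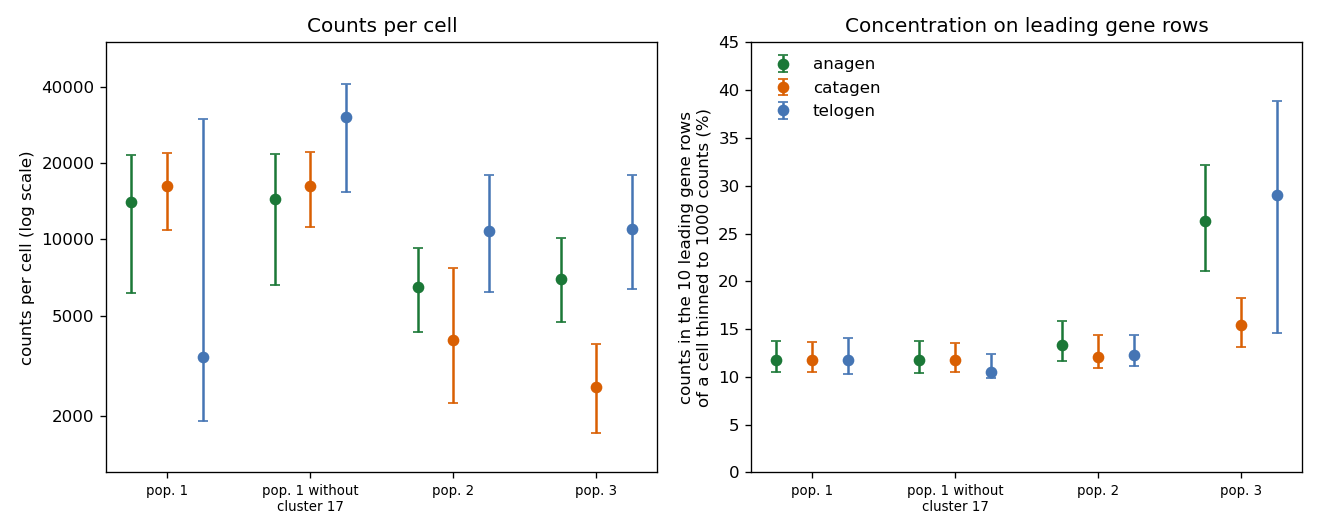
Points are medians over cells and bars run between the quartiles, by stage, for populations 1, 2 and 3 and for population 1 without cluster 17; the left axis is counts per cell on a log scale and the right axis the percent of thinned counts in the 10 leading gene rows. In population 3 the right panel shows 15.4% in catagen against 26.3% in anagen and 29% in telogen.

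The fourth comparison asks how the level of each gene row differed between stages. Over all cells, 2314 gene rows were compared. Catagen and anagen lay closest, with a standard deviation of log2 ratios of 0.56, against 0.74 for telogen over catagen and 0.79 for telogen over anagen. Population 3 had another order, with 0.77 for catagen over anagen, 0.62 for telogen over catagen and 0.72 for telogen over anagen. At equal cells and counts these were 0.9, 0.76 and 0.89, where the first and last overlapped in range. The cell names of anagen and catagen share a first prefix that telogen lacks, so handling that they had in common cannot be told apart from the stage. The median log2 ratio was 0.02 for catagen over anagen, −0.23 for telogen over catagen and −0.21 for telogen over anagen. Of the gene rows, 2.55% were at least 2-fold higher and 2.98% at least 2-fold lower in catagen than in anagen. The shares were 7.74 and 5.49% for telogen over catagen and 8.17 and 5.36% for telogen over anagen. The part of these that was higher depended on the scaling: it was 46.1, 58.5 and 60.4% here and 30.5, 70.2 and 65.5% with median-ratio scaling. Summed counts gave 26.5% for catagen over anagen.

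The shares of the populations alone, with each population held at its mean over the stages, gave ratios with standard deviations of 0.24, 0.45 and 0.42. Taking them away left 76.6% of the variance of the log2 ratios for catagen over anagen, 59.3% for telogen over catagen and 68.9% for telogen over anagen.

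Within populations, catagen over anagen varied least in population 1, where 1.43% of 2165 gene rows were at least 2-fold higher and 1.62% lower, and most in population 3, with 9.83 and 5.09% of 2238. Population 2 had 2.49 and 3.96% of 2245. The populations differ in cells and depth. With 155 cells per stage thinned to 1000 counts, the mean standard deviation of log2 ratios over 20 draws was 0.69 in population 1 (range 0.66 to 0.71), 0.77 in population 2 (0.73 to 0.8) and 0.9 in population 3 (0.88 to 0.92), against 0.51 in each between 2 draws of anagen cells. Population 3 had only 169 catagen cells to draw from, so its draws shared most cells and its range is narrow by construction. The direction in population 3 rested on the scaling. Its median log2 ratio was 0.28, or −0.11 with median-ratio scaling, and the part of the 2-fold rows that was higher was 65.9%, or 26.9% with median-ratio scaling and 52.6% with totals without the 50 highest rows. In population 2 that part was 38.6%, or 23.4% with median-ratio scaling. For telogen over catagen it was 52.1, 45.9 and 37.1% in populations 1, 2 and 3, or 74.5, 61 and 74.4% with median-ratio scaling, which moved the medians from −0.19, −0.24 and −0.25 to 0.13, −0.02 and 0.1. For telogen over anagen it was 51.7, 45.3 and 51.6%, or 77, 49.8 and 49.6%. In population 1 both values also rested on cluster 17: without it 65.4% of the 2-fold rows were higher in telogen than in catagen and 71.6% higher than in anagen, and the lower rows went from 6.24 to 2.88% and from 7.21 to 2.61% of gene rows. No direction over the gene rows as a whole is therefore given for these comparisons.

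Ratios of the same gene row in different populations had Pearson correlations across rows of 0.64 to 0.77 for catagen over anagen, 0.47 to 0.65 for telogen over catagen and 0.61 to 0.83 for telogen over anagen. Spearman correlations were lower, at 0.38 to 0.57, 0.32 to 0.47 and 0.22 to 0.6. The share of gene rows with the same sign ran from 56.8% (telogen over anagen, populations 1 and 3) to 70.2% (telogen over catagen, populations 1 and 2). Gene rows are not independent replicates, and the populations of a stage came from the same library.

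By the rule on size, 2 gene rows in each direction are named for catagen against anagen, among rows above 0 in both libraries. That restriction was made after the data were seen, since a row listed at 0 gives no ratio. Row 6078 held 6 counts in anagen and 2858 in catagen, a ratio of summed counts of 613 (95% interval 281 to 1673), and 621 in telogen. In catagen it stood at 4.79 counts per 10000 over all cells and at 0.209, 0.195 and 0.103 in populations 1, 2 and 3. Most of its catagen level thus lay in the small populations, which held 8.09% of catagen cells. Its interval takes counts as independent, which counts gathered in few cells are not. Row 14407 held 7 counts in anagen and 403 in catagen, a ratio of 74.1 (35.6 to 186), and 264 in telogen. Row 14416 held 7756 counts in anagen and 6 in catagen, a ratio of 1004 (461 to 2737), and 5 in telogen. It stood at 2.65, 2.44 and 0.26 counts per 10000 in anagen cells of populations 1, 2 and 3. Row 9741 held 2117 counts in anagen and 14 in catagen, a ratio of 117 (69.8 to 215), and 103 in telogen. It stood at 0.08, 0.643 and 3.51 counts per 10000 in anagen cells of populations 1, 2 and 3. The counts above are not scaled for the size of the libraries. Over all catagen cells these rows stood, in the order named, at 4.79, 0.152, 0.001 and 0.009 counts per 10000. Over all telogen cells they stood at 1.03, 0.293, 0.002 and 0.09, so row 14407, with fewer counts in telogen than in catagen, was higher there per 10000.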

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

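The tests of the share of population 1, of free RNA and its dilution, and of batch in the parting of population 3 were chosen after the result was seen, and the common count floor was itself chosen after seeing the data. Dilution was tested after the first test on free RNA had been run, and the intervals used in judging the parting and the gene rows of population 1 used in judging free RNA were added after their values were seen.

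Median counts per cell moved opposite ways between stages in different populations. From catagen to telogen the ratio was 2.69 in population 2 and 4.22 in population 3, against 0.21 in population 1. From anagen to telogen it was 1.67 in population 2 and 1.58 in population 3, against 0.25 in population 1. The difference between the populations was not tested. It rests on cluster 17 and on the shallow cells listed. Without cluster 17 the median of population 1 in telogen was 30447.5 counts, above 14434 in anagen and 16303 in catagen. Above the common floor, with cluster 17 kept, the medians were 13997 in anagen, 16956 in catagen and 24020 in telogen.

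Population 3 parted by stage more than populations 1 and 2. With every cell thinned to 1000 counts, 82.7% of the neighbours of its anagen cells were from anagen (exact binomial 95% interval over cells 76.3 to 88.2), against 44 and 44.1% in populations 1 and 2. Without the 1294 gene rows that shifted at least 1.5-fold the same way in those populations it was 81.4% (74.7 to 86.7); the 41.4 and 40.2% of populations 1 and 2 were lowered by construction. The 82.7 and 81.4% lie above the 65% that a difference in depth or a shift shared by the whole library would need as the whole cause, and above the 80% set in advance, although their intervals reach below that 80%. These intervals treat cells as independent, although cells share neighbours, so they do not measure the spread of the neighbour share. With 1 library per stage, biology of the stage and batch cannot be told apart.

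Population 1 was smaller in telogen. Above a common floor of 2341 counts its telogen share was 15.42% (12.71 to 18.45) against 53.46% in anagen. The smaller share was thus also seen among cells of the same lowest count. The test set for different lowest counts could not have come out otherwise with the main clusters. Had all 157 telogen cells of population 1 stayed among the 642 above the floor, the share would still have missed the level set. The floor left 101 of them, so the test does not decide on that cause. Loss of cells during tissue dissociation stays open, since all 157 telogen cells of population 1 came from 1 suspension, and so does a biological difference between the stages.

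Catagen cells of population 3 had a lower share of counts in their 10 leading gene rows than anagen cells. Above the common floor their median of 15.5% (quartiles 13.05 and 18.9) was still 58.9% of that in anagen (26.3%, quartiles 21.1 and 32.15), which argues against shallow cells as the cause. The first test on free RNA from other cells was undecided: in catagen cells of population 3, gene rows of population 2 stood at 13.1% of their mean over all catagen cells, under the 20% set for the test, but those of population 1 at 24.8%, above it, and the test takes the mean of all cells for the free RNA. Dilution alone would lower the gene rows of population 3 together. Of them 65.8% (57.7 to 73.3, with gene rows taken as independent), or 50.7% with median-ratio scaling, stood at least as high in catagen as in anagen. Levels are shares of a cell's counts, so a fall of the leading rows raises the others. The rows were also chosen on means that include catagen. The test therefore speaks at most against dilution as the only cause. Free RNA as a part of the cause, batch and a biological difference of the stage stay open.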

How the results depend on the processing

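The common count floor, the highest doublet scores left out, clustering without stage-shifted gene rows, leaving out cluster 17, the scalings of the gene rows of population 3, and equal cells and counts, were chosen after seeing the data. Alternative values of population shares, own-stage neighbours over all cells and 2-fold shares over all cells numbered 270. Of these, 241 stayed within the interval or within 1.5 times the main value and 29 moved. Of 181 other values, 36 moved. The median count of population 1 in telogen, 3436 and 24020 with the common count floor, was not counted among the moved. Clusters of each alternative were placed by the main population that held most of their cells, so a share moved only where clusters crossed populations or cells were left out. No reported share moved with at least 500 detected gene rows, doublets left out or resolutions of 0.5 and 2. Of 6415 cells, the minimum of 500 gene rows kept 6414 and leaving doublets out kept 6405, so these could hardly move a share. With libraries clustered on their own, population 8 was at 1.21% in catagen and populations 5 and 9 at 0% in telogen; with the highest doublet scores left out, population 5 was at 0.22% in anagen and population 8 at 0.16% in catagen; the cause was not tested. With the common count floor, population 1 was at 49.21% in catagen and 15.42% in telogen, population 2 at 39.52% in catagen, population 3 at 4.92% in catagen and 32.24% in telogen, population 5 at 0.72% in catagen, population 8 at 0% in both, and own-stage neighbours of anagen cells were at 65.46%; by construction 539 catagen, 146 telogen and 0 anagen cells were left out. With the same clusters kept, population 5 was at 0.72% and population 8 at 0.1% in catagen, and population 8 at 1.4% in telogen. Thinned to 1000 counts, telogen was at 15.32% for population 1 and 44.03% for population 2, and own-stage neighbours at 54.3, 63.26 and 66.49% in anagen, catagen and telogen; the cause was not tested. Without cluster 17, telogen was at 10.75% for population 1 and 45.12% for population 2. Without stage-shifted gene rows, own-stage neighbours were at 45.85, 49.99 and 66.81%, by construction. In population 3, also by construction, they went from 93.83 to 63.26% in anagen, from 84.92 to 41.17% in catagen and from 83.37 to 77.54% in telogen. Its catagen cells thus lay near the 33.3% of equal mixing. With summed counts, 1.63% of gene rows were at least 2-fold higher and 4.53% lower in catagen than in anagen; the cause was not tested. Populations 1 and 3 kept their order of stages under each alternative. Alternatives for gene lists, cycling cells, naming clusters per library and totals without mitochondrial and ribosomal genes were not run, since the file names no genes. No paired analysis was possible because each stage has 1 library and no result comes from a test.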

Other observations

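The test in this part was chosen before its value was seen, but after the level of row 16359 in the anagen populations was known.

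Gene rows of population 11, the 24 cells found in anagen alone, were seen at a low level throughout that library: 99.76% of the 2969 other anagen cells held a count of the 28 rows listed at 0 in catagen and telogen. The 50 rows of population 11 summed to 13.58, 17.37 and 16.35 counts per 10000 in anagen cells of populations 1, 2 and 3, or 0.7, 0.89 and 0.84% of their level in population 11. A candidate explanation is free RNA from population 11. One source would keep its gene rows in the same order everywhere, with a rank correlation across rows of at least 0.7 set in advance; the correlations were 0.56, 0.54 and 0.56, between that bound and the 0.4 set against it, so the test did not decide. Gene rows are not independent replicates, and low expression of these rows in all anagen cells, or a filter that removed them from the other libraries, stays open. Catagen and telogen both list rows found in as few as 3 cells. A filter on the number of cells alone would thus have hidden only rows found in very few cells there.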
